A study of Mus musculus with 2 samples.

How the data were processed

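RNA of M210B4 cells was measured on 2 Affymetrix Mouse Gene 2.0 ST arrays, 1 from cells treated with a CD84-activating antibody and 1 from cells treated with an IgG1 isotype control. Per the labels' protocols, 200000 cells per treatment were kept at 37 °C and 5% CO2 in medium with 2% serum for 24 h, and 200 ng of total RNA was labelled with biotin through an Affymetrix WT cDNA synthesis and labelling kit. The deposited table holds log2 expression values, 1 per probe set and array. Per the submitters' processing notes, RMA and Partek were used, with no versions or settings. RMA is in general a background correction, a quantile normalization and a summary of probes into probe sets. Which arrays were normalized together, and the annotation version used for the summary, are not given in the sources used here. The log2 scale and the 1-colour centring were inferred from the values, which run from 1.82 to 13.8 with medians of 4.87 and 4.88. Array differences of dim probe sets tend to be compressed towards 0, so folds of low genes can be understated. With 1 array per group they can also be overstated by noise. The standard deviation of the differences was 0.62 for genes with a mean level under 5 and 0.22 for those over 11. The upper quartiles, 6.94 and 6.82, differ, so the probe set values are not identically distributed on the arrays.

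Probe sets were named through GEO's platform annotation. Of 41345 probe sets 23521 have 1 gene symbol, 1814 have several and 16010 are not named in it. Probe sets with several symbols were not used for gene results, which is why some well-known members of the gene lists do not appear. Gene IDs of 23328 single-symbol probe sets were found in a RefSeq gene table (GRCm38.p6) and 0 of their symbols differed. No coordinates are given because the array's build is not named in the sources used here. The single-symbol probe sets cover 22180 genes, and 1082 of them have more than 1 probe set. Such a gene is represented by its brightest probe set.

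With 1 array per group no test, standard error or p-value exists, so the results are sizes described by rules that were fixed before the data were examined. The difference is the anti-CD84 log2 value minus the IgG1 value. The detection level, 4.84, is the 95th percentile of the values of 1405 olfactory and vomeronasal receptor genes on both arrays, since a stromal line is not thought to use these genes. It is a working level and not a call per probe. A gene was detected when above it on at least 1 array. Where 1 array was below, the fold was counted from the detection level and written "at least". Differences of 2-fold and 1.5-fold were counted. For scale, detected chosen genes were set against the 500 detected genes nearest in mean level, by the differences as measured. Files that hold probe-level intensities were not used here.

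In all, 40 gene lists were fixed beforehand: pathways of CD84, checkpoint, interferon, antigen presentation, cytokine, NF-kB, Akt and mTOR, p53, apoptosis, cell cycle, stress, metabolic and matrix genes, RNA classes, and markers of the cell types a marrow culture could hold. A symbol may belong to several lists. For each list with at least 5 detected members, the median difference was ranked as a percentile among 10000 random lists of detected genes of the same size, matched in 20 bins of mean level. A list was said to stand apart in the bottom or top 0.5% of its random lists. This describes these 2 arrays only, and gene-to-gene correlation makes real lists more variable than random ones. Named genes were 11 chosen genes, the 14 detected genes with the highest and the 14 with the lowest signed difference (leaving out predicted and clone names, small RNAs, sensory receptors and antigen receptor segments), and up to 4 members per list by absolute difference, or 2 where no member reached 1.5-fold. Values below the detection level have no order, so the ranking of genes with 1 array below it carries no meaning.

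The alternatives were the difference centred on its median, a loess curve of difference on level removed (limma, span 0.4), quantile normalization of the 2 columns, no level filter, a stricter level (the 75th percentile of all values, 6.88), the mean of all probe sets of a gene, and values floored at the detection level. Requiring both arrays above the detection level was added after seeing the data. Leaving out a replicate could not be done with 1 array per group. The counting and list steps were checked on simulated data for this comparison with 13290 genes and noise of 0.25 (SD, log2), which is below the observed spread of 0.44, so this checks the computation and gives no error rate for the counts reported. All 200 genes changed by 2 on the log2 scale were recovered at 2-fold, with 1 unchanged gene counted. A 25-gene list shifted by 0.4 reached percentile 100, and 3 of 200 unshifted lists fell outside the bounds. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.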

Results

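The transcriptome of M210B4 cells, an established mouse bone marrow stromal line, was compared between a culture exposed for 24 h to an antibody that activates CD84 and a culture exposed for the same time to an IgG1 isotype antibody. CD84 is a cell-surface receptor of the SLAM family that binds itself on neighbouring cells. Each condition was measured on 1 Affymetrix Mouse Gene 2.0 ST array, a 1-colour array that reports 1 intensity summary per probe set, from cells kept in medium with 2% serum. Every difference below is therefore the difference between 2 arrays, with no replicate check, no standard error and no p-value, and the precision is limited by the number of arrays. The arrays held 41345 probe sets each. Their median log2 values were 4.87 (anti-CD84) and 4.88 (IgG1), and 12470 and 12585 genes respectively lay above a detection level of 4.84. Across all probe sets the arrays correlated with a Pearson r of 0.967.

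The question behind the comparison was which genes differ after CD84 activation. Of 13290 genes detected on at least 1 array, 263 were at least 2-fold higher and 190 at least 2-fold lower after anti-CD84 than after IgG1. With the difference centred on the median of the detected genes, which lay at 0.09 on the log2 scale, the split was 188 higher and 252 lower. Of the 453 genes, 221 were below the detection level on 1 of the arrays, which leaves 171 higher and 61 lower genes that were measured on both. At 1.5-fold, 1427 genes were higher and 850 lower, and with the difference centred 1024 were higher and 1128 lower, so the excess of higher genes depended on the scaling at both thresholds. The log2 differences had a standard deviation of 0.44, and 95% of them lay between -0.83 and 0.95. The spread narrowed with level, from 0.62 for genes with a mean log2 value under 5 to 0.22 for those over 11. For 375 genes with a pair of distinct probe sets above the detection level on both arrays, the differences of the pair correlated with an r of 0.08 and a Spearman rho of 0.12 across genes, which are not independent replicates, and 53.9% of pairs had the same sign. For the 107 pairs with both levels above 7, r and rho were both 0.23. For the 74 pairs with both levels above 8 they were 0.13 and 0.24. For the 112 pairs with levels within 1 log2 of each other they were 0.03 and 0.11. Whether the probe sets of a pair target the same transcripts was not examined. Among the 44 of all 375 genes whose brighter probe set differed by 1.5-fold or more, the other probe set had the same sign in 23. In 8 of these it was also past 1.5-fold. For pairs with levels within 1 log2 these counts were 6 and 1 of 16, and for pairs above 7 they were 4 and 3 of 7. If the probe sets of a pair target the same transcripts, their disagreement gives a standard deviation of 0.40 for the difference of a single probe set. That is near the 0.44 of all detected genes.

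Among 11 genes chosen before the data were examined for their place in CD84 signalling or in the support of lymphoid cells by stroma, Cxcl12 had the largest difference of those measured on both arrays. Cxcl12, the stromal chemokine that retains haematopoietic cells in the marrow, was 2.15-fold higher after anti-CD84 (log2 10.29 against 9.19), and 0 of the 500 detected genes nearest to it in level differed by as much in either direction. Cd80, a ligand of CD28 and CTLA-4, was 1.57-fold higher (10.26 against 9.60), a size reached by 31 of its 500 neighbours in level. Cd274, which encodes the PD-1 ligand PD-L1, was at 5.33 after anti-CD84 and below the detection level, at 4.56, after IgG1. That makes it at least 1.40-fold higher, and 46 of its 500 neighbours in level had a measured difference as large. Tnfsf13b, the B cell survival factor BAFF, went the other way, at 4.52 and so below the detection level after anti-CD84 against 5.35. It was at least 1.43-fold lower, and 31 of its 500 neighbours had a measured difference as large. Mif (10.72 against 10.66) and Vcam1 (8.14 against 8.13) had log2 differences of 0.06 and 0.01. Cd84 itself was below the detection level on both arrays, at 4.15 and 3.82, so no fold is given for it. Pdcd1lg2 (4.77 and 4.65), Sh2d1a (4.46 and 4.26), Il6 (3.92 and 4.17) and Cd86 (3.51 and 3.76) were likewise below it on both. Where 1 array was below the detection level, a fold is given as "at least", counted from that level. It allows for no noise in the brighter value and so is not a statistical bound. Counts of genes past 2-fold or 1.5-fold use the values as measured on both arrays.

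**Figure D1:**
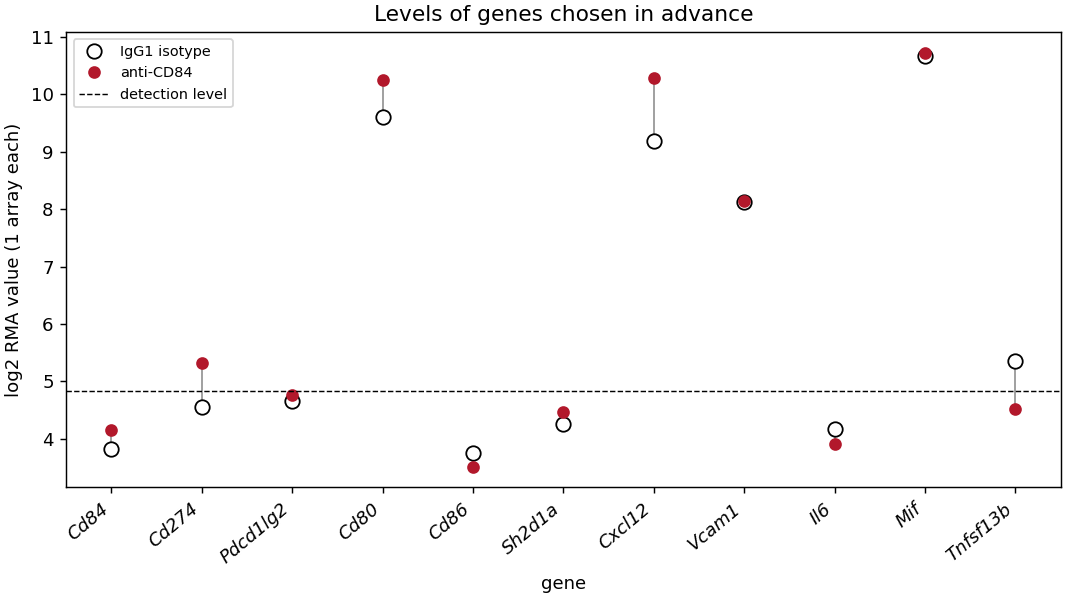
Log2 RMA values of the 11 genes chosen in advance, with the IgG1 array as open and the anti-CD84 array as filled circles (1 array each, no error bars) and the detection level of 4.84 as a dashed line. Cxcl12 stands at 10.29 against 9.19, while Cd84, Pdcd1lg2, Cd86, Sh2d1a and Il6 lie below the line on both arrays.

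Gstp2, Dio2 and Cd59a were over 3-fold higher after anti-CD84, and Pilrb1, Prps1 and Wasf1 over 3-fold lower, all above the detection level on both arrays. Of the 14 named for the highest differences, 6 were above the detection level on both arrays. Gstp2, a glutathione S-transferase of the pi class, was 5.16-fold higher (10.48 against 8.11), but its close paralogue Gstp1, looked up after the values were seen, differed by 0.39 on the log2 scale, and probes of so similar a pair can share signal. Dio2, the deiodinase that activates thyroid hormone, was 4.12-fold higher, and Cd59a, the membrane inhibitor of complement lysis, 3.81-fold higher. Pi15, a peptidase inhibitor, Zfp729a, a zinc finger gene, and the pseudogene Stxbp3-ps were 3.10-fold, 3.05-fold and 2.99-fold higher. The other 8 were below the detection level after IgG1. Of these, Mill2, an MHC class I-like gene, was at least 3.10-fold higher, Mmp13, the interstitial collagenase, at least 2.92-fold, and Apol10b, of the apolipoprotein L family, at least 2.46-fold. Zfp955a (at least 2.75-fold), Clvs2 (at least 2.59-fold), Zfp974 (at least 2.08-fold) and C1s1, a protease of the classical complement pathway (at least 1.78-fold), were also among them. For Cisd3, at least 2.43-fold higher, a further probe set differed by 0.72 in the same direction.

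Of the 14 genes named for the lowest differences, 4 were above the detection level on both arrays. Pilrb1, a paired immunoglobulin-like receptor, was 4.09-fold lower (5.27 against 7.30). Prps1, which makes the ribose precursor of nucleotides, was 3.63-fold lower (7.04 against 8.90), Wasf1, a regulator of actin polymerisation, 3.56-fold lower (6.23 against 8.06), and Acaa1a, the peroxisomal thiolase, 3.19-fold lower (4.98 against 6.65). The remaining 10 were below the detection level after anti-CD84. Gbp5, an interferon-inducible GTPase, was at least 3.12-fold lower, Prlh and Trp53rka at least 2.96-fold, Stra6, the receptor for retinol-binding protein, at least 2.93-fold, and Lta, which encodes lymphotoxin alpha, at least 1.96-fold. Rps15 was at least 2.13-fold lower, at log2 values of 3.73 and 5.93, below most other ribosomal protein genes on these arrays. Stfa2 (at least 1.63-fold), the histone variant gene Macroh2a2 (at least 1.36-fold), Zfp820 (at least 1.25-fold) and Mcpt-ps1 (at least 1.06-fold) completed this group.

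**Figure D2:**
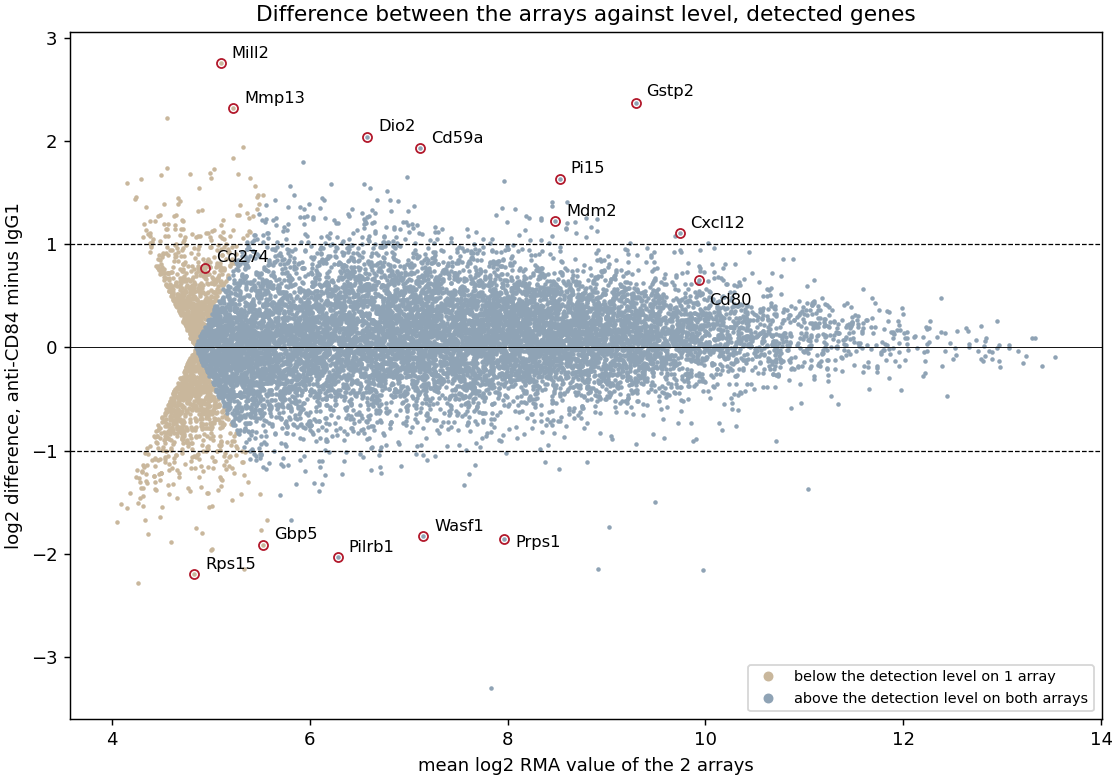
Log2 difference (anti-CD84 minus IgG1) against the mean log2 RMA value for each of the 13290 detected genes, coloured by whether both arrays were above the detection level; dashed lines mark 2-fold. Gstp2, Cd59a, Pi15, Mdm2 and Cxcl12 stand above the upper line at levels where few genes do, and the widest scatter lies at low levels.

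Genes of the p53 response were higher as a group after anti-CD84. Of the 24 detected members of the list, 8 were at least 1.5-fold higher, 0 were 1.5-fold lower and 16 lay within 1.5-fold. Mdm2, the ubiquitin ligase that restrains p53, was 2.33-fold higher (9.09 against 7.87). Eda2r, of the TNF receptor superfamily, was 1.81-fold higher, the stress sensor Sesn1 1.78-fold higher, and Cdkn1a, the cell cycle inhibitor p21, 1.65-fold higher (11.04 against 10.32). The median difference was 0.46, above all 10000 random lists of the same size and matched level, whose median was 0.10. Cd80, 1 of the 8, is also in this list. Of the 38 lists ranked in this way, p53 targets alone lay in the top 0.5% of their random lists and small nucleolar RNAs alone in the bottom 0.5%. Chance would put 0.38 lists there if lists were random sets of genes, which co-regulated genes are not.

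The cell cycle and apoptosis lists were not set apart. The G2/M and mitosis list had a median of 0.08 (percentile 35.7) and 0 of 33 members differed by 1.5-fold, with Mki67 at 0.41 and Cenpf at -0.36. In the S phase and DNA replication list the median was 0.00 and the mean -0.02 (percentile 6.81). Of its 27 members 2 were 1.5-fold lower, Tipin 1.70-fold and Chaf1a 1.59-fold, and 0 were higher. Signs of these medians change when the arrays are rescaled. Among 21 detected apoptosis regulators 5 were 1.5-fold higher and 2 lower (median 0.10, percentile 54.4). The death effector Casp8 was 1.77-fold higher, the pro-apoptotic Bcl2l11 1.82-fold higher and the inhibitor Birc2 1.76-fold lower, while Bcl2a1a was at least 1.05-fold higher.

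**Figure D3:**
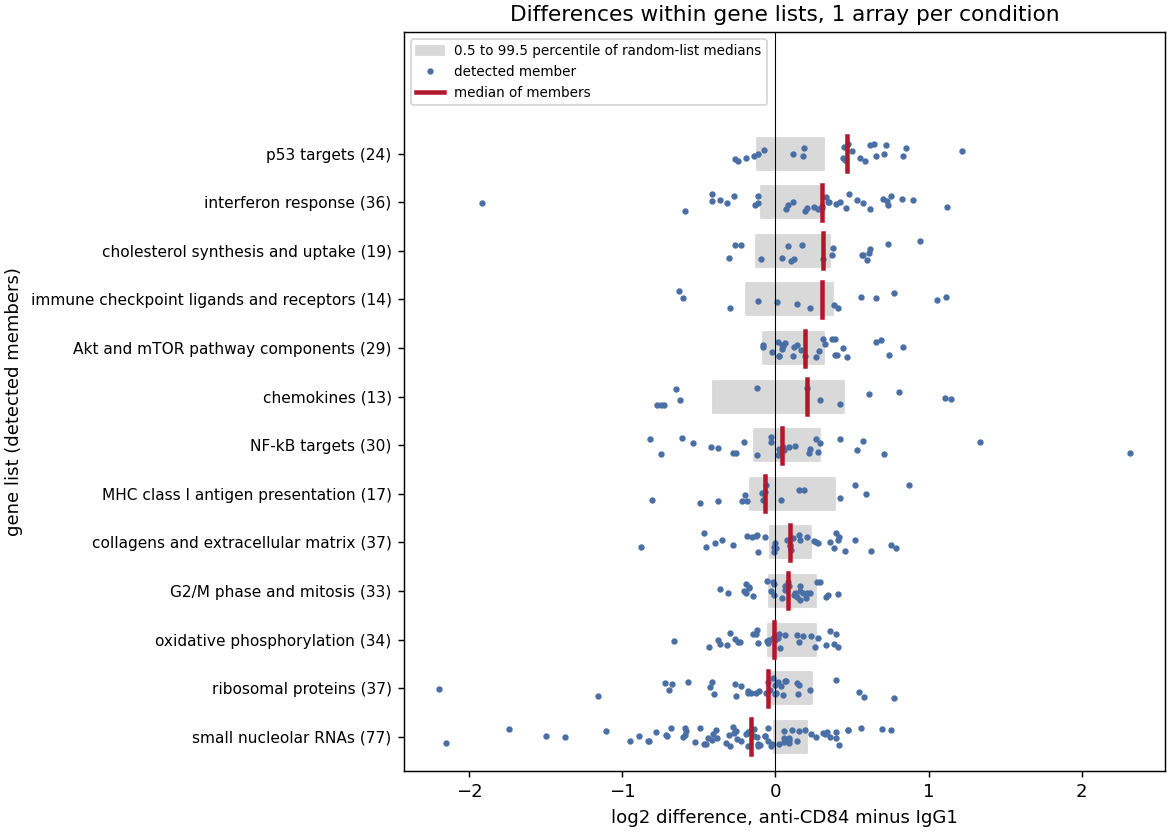
Log2 difference (anti-CD84 minus IgG1) of each detected member (points) of 13 gene lists, with the median (vertical bar) and the range of the medians of 10000 level-matched random lists without the outer 0.5% on each side (grey); numbers in brackets are detected members. The p53 median of 0.46 lies right of its grey range and the small nucleolar RNA median of -0.16 lies left of it.

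Immune checkpoint genes had mixed differences, with the larger ones upward. Of 14 detected members 4 were at least 1.5-fold higher, 2 lower and 8 within that range (median 0.31, percentile 97.1). Havcr2, which encodes TIM-3, was 2.16-fold higher (6.76 against 5.65), and Cd200, an inhibitory surface ligand, 2.08-fold higher (7.48 against 6.43). Cd274 and Cd80 were the other 2, and the 2 lower members, named after the values were seen, were Lgals3 (-0.63) and Nectin2 (-0.60). The interferon response list had a median of 0.30 at percentile 99.4, just inside the bound. Of its 36 detected members 8 were 1.5-fold higher and 2 lower. Stat2, a transcription factor of type I interferon signalling, was 1.77-fold higher and Cmpk2 1.86-fold higher, Ddx60 was at least 1.79-fold higher, and Gbp5 was the lowest member. Among 17 MHC class I antigen presentation genes 2 were higher, 1 lower and 14 within 1.5-fold, with a median of -0.07 but a mean of 0.01 (percentile 3.52). The peptide editor Tapbpl was 1.83-fold higher and H2-M3 1.51-fold higher, and the immunoproteasome subunit Psmb9 was 1.75-fold lower. For Tapbp, 1.43-fold higher, a further probe set differed by -0.20. In the SLAM family list 5 of 12 measured members were detected (median 0.44, percentile 90.5), and the median was 0.07 with values floored at the detection level. Apart from Fyn (8.35 and 8.39, named after the values were seen), the detected members lay near that level. Slamf1 was at least 1.06-fold higher, Cd244a at least 1.18-fold and Slamf6 at least 1.05-fold, and Slamf8 at least 1.09-fold lower. Fc gamma receptor and antibody-sensing genes, 5 of them detected, had a median of 0.44 (percentile 94.8), which became 0.05 with values floored at the detection level and negative with undetected members included. Fcgrt, the neonatal Fc receptor, was 1.42-fold higher (10.10 against 9.60), Fcgr4 at least 1.29-fold and Fcer1g at least 1.04-fold higher, and Trim21 had a difference of -0.24.

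Chemokines split in both directions, with 4 of 13 detected members at least 1.5-fold higher and 5 lower (median 0.21, percentile 86.9). Of these, only Cxcl12 and Cx3cl1 among the higher and Ccl2 and Ccl7 among the lower were above the detection level on both arrays. Beside Cxcl12, Cx3cl1, the membrane-bound chemokine fractalkine, was 2.21-fold higher (8.16 against 7.01) and Ccl5 at least 1.22-fold higher, whereas Cxcl13 was at least 1.58-fold lower. Among 26 detected stromal cytokines and growth factors 3 were higher and 3 lower (median 0.18, percentile 85.4). Bmp4 was 1.89-fold higher, Hgf, the hepatocyte growth factor, 1.82-fold higher and Il15, a survival cytokine for NK and memory T cells, at least 1.47-fold higher, while Csf2, which encodes GM-CSF, was at least 1.27-fold lower. NF-kB targets had 3 of 30 members higher and 3 lower (median 0.04, percentile 33.8, of either sign depending on the scaling). They included Mmp13, the prostaglandin E synthase Ptges, 2.52-fold higher (7.29 against 5.96), Birc2, and the monocyte chemoattractant Ccl2, 1.68-fold lower. Of 12 detected marrow stromal and progenitor markers 3 were higher and 0 lower (median 0.18, percentile 70.4). With Cxcl12 these were the platelet-derived growth factor receptor Pdgfra, 1.89-fold higher (10.21 against 9.29), and the transcription factor Foxc1, 1.68-fold higher, and Thy1 was at least 1.08-fold lower.

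Signalling and matrix lists had medians inside the range of their random lists. Among 29 Akt and mTOR pathway components 4 were 1.5-fold higher and 0 lower (median 0.19, percentile 86.0), namely Sesn1, Mtor (1.67-fold), the insulin receptor substrate Irs1 (1.61-fold) and Foxo3 (1.58-fold). Immediate early genes had 4 of 33 members higher and 1 lower (median 0.02, percentile 8.62, with a sign that changes with the scaling). Phlda1 and Nr4a2 were both 1.73-fold higher, Dusp1, a MAP kinase phosphatase, 1.61-fold higher and Spry2 1.54-fold lower. In the list of YAP and SRF targets 2 of 24 were lower and 0 higher (median 0.13, percentile 69.2), the smooth muscle and skeletal actins Actg2, 1.81-fold, and Acta1, 1.71-fold; Axl was 1.41-fold and Edn1 at least 1.36-fold higher. TGF-beta targets had 3 of 18 members higher (median 0.16, percentile 77.0), with Smad6 at 1.83-fold, Tgfbi at 1.58-fold and Postn at 1.54-fold, and Itgb3 at 1.37-fold. Of 37 collagen and matrix genes 3 were higher and 1 lower (median 0.10, near the middle of its random lists). The proteoglycans Vcan and Dcn were 1.73-fold and 1.69-fold higher, and the basement membrane collagen Col4a1 was 1.83-fold lower (9.14 against 10.02). Matrix proteases had 3 of 19 higher and 1 lower (median 0.22, percentile 92.0). Beside Mmp13, the aggrecanase Adamts4 was at least 1.88-fold higher and Adamts12 1.78-fold higher, and Mmp10 was at least 1.45-fold lower. Adhesion molecules and integrins had 1 of 26 higher, Itgb8 (1.52-fold), and 1 lower, Sele (at least 1.06-fold), with Sdc4 at 1.38-fold higher (median 0.12, percentile 68.3).

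Among the metabolic and stress lists, cholesterol synthesis had the most members 1.5-fold higher, and its median still lay inside the range of its random lists. Of 19 cholesterol synthesis and uptake genes 5 were 1.5-fold higher and 0 lower (median 0.31, percentile 97.9). Dhcr7, which makes cholesterol from its last precursor, was 1.92-fold higher, Tm7sf2 1.66-fold, Mvd 1.54-fold and Fdft1 1.53-fold. Fatty acid synthesis had 1 of 12 members higher, the elongase Elovl6 at 1.76-fold (median 0.13, percentile 63.2), with Acaca at 1.37-fold and Srebf1 at 1.35-fold. NRF2 targets had 2 of 20 higher and 0 lower (median 0.10, percentile 45.9), catalase (Cat) at 1.93-fold (10.21 against 9.27) and Nqo1 at 1.61-fold. Hypoxia and glycolysis genes had 1 of 27 higher, the lactate exporter Slc16a3 at 1.67-fold, and 1 lower, Higd1a at 1.64-fold (median 0.07, percentile 35.9). Among 36 ATF4 targets 1 was lower, Slc7a3 (at least 1.05-fold), and Pck2 was 1.47-fold higher and Psph 1.47-fold lower (median 0.03, percentile 14.8). The unfolded protein response list had 0 of 18 members 1.5-fold apart (median 0.11, percentile 50.5), with Dnajb9 at 1.32-fold higher. Heat shock proteins had 1 of 17 higher, Hspb8 at 1.83-fold, and a median of -0.05 (percentile 3.29), with Ahsa1 1.46-fold lower. Signs of the hypoxia and ATF4 medians change with the scaling.

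Small nucleolar RNAs, most of which act on ribosomal RNA, were lower as a group after anti-CD84. So was a set of 21 other short or miscellaneous non-coding RNAs. The small nucleolar RNA list, fixed by name prefixes, had 77 detected members: 71 Snora and Snord genes, 5 Cajal body RNAs (Scarna) and the 5S ribosomal RNA gene n-R5s136 (0.31). Of these 16 were at least 1.5-fold lower and 2 higher, and the median of -0.16 lay below all 10000 random lists, whose median was 0.10. The Snora and Snord genes alone, a subset chosen after the values were seen, had a median of -0.17. The set of 21, of which 10 have established names, was also chosen afterwards. Its median was -0.32 (percentile 0.01), while that of microRNA precursors was 0.10. Snora75 was 4.45-fold lower (8.90 against 11.05), Snord118 3.33-fold, Snora73b 2.83-fold and Snora62 2.60-fold lower. Ribosomal protein genes had 5 of 37 members lower and 1 higher (median -0.05, percentile 0.56), with Rps7 2.23-fold lower, Rpl22 1.65-fold lower and Rpl6 1.71-fold higher. The members past 1.5-fold were dimmer than most of this list, with Rps7 at 6.13 against 7.29 while Rps6 was at 12.67 against 12.66. How well such dim probe sets report their genes was not examined. Oxidative phosphorylation genes had 1 of 34 members lower, Cox7b at 1.58-fold, for which a further probe set differed by 0.70 the other way (median -0.01, percentile 3.20, of either sign depending on the setting). Ribosome biogenesis genes had 2 of 26 higher, Odc1 at 1.68-fold and Wdr74 at 1.61-fold (median 0.06, percentile 24.3, with a sign that changes with the scaling). Replication-dependent histones had 2 of 18 higher and 3 lower (median -0.11, percentile 3.62), with H2ac1 1.75-fold and H2bc3 1.73-fold lower. MicroRNA precursors had 29 of 169 detected members higher and 23 lower (median 0.10, percentile 85.9, with a sign that changes with the level filter). Over the alternatives their percentile ran from 1.7 to 86.4. Mir3091 was at least 1.98-fold higher and Mir335 at least 1.46-fold lower.

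Of the macrophage, lymphocyte and endothelial markers, most were below the detection level on both arrays. Of 20 macrophage and monocyte markers 8 were detected, 2 of them 1.5-fold higher (median 0.15, percentile 74.8). That median was 0.01 with values floored at the detection level and negative with undetected members included. Cx3cr1 was 1.55-fold higher (5.71 against 5.08), Csf1r at least 1.02-fold and Cd14 at least 1.12-fold higher, and Tyrobp at least 1.01-fold lower. Of 14 B and T lymphocyte markers 5 were detected (median -0.18, percentile 19.8), with Cd5 at least 1.44-fold higher, Cd3d at least 1.20-fold lower and Cd8b1 at least 1.12-fold lower. Of 12 endothelial markers 4 were detected, with a median of -0.33; the 2 that were 1.5-fold lower, named after the values were seen, were Cdh5 (4.61 against 5.56) and Pecam1 (4.32 against 4.99), both under the detection level after anti-CD84. Of 7 erythroid and megakaryocyte markers 4 were detected (median 0.00, mean -0.11). Adipocyte markers, 13 of 20 detected, had 0 members 1.5-fold apart, a median of 0.10 and a mean of -0.05 (percentile 55.4), with Fabp5 1.42-fold lower. Osteoblast and chondrocyte markers, 9 of 15 detected, had a median of -0.27 (percentile 2.23), which became -0.02 with the mean of all probe sets of a gene, with the cartilage collagen Col2a1 1.85-fold lower (8.61 against 9.49), the chondrogenic factor Sox9 1.42-fold lower and Postn higher. Olfactory and vomeronasal receptors, which set the detection level, had 93 of 1405 members above it on at least 1 array, 19 of them 1.5-fold higher and 19 lower (median -0.04, percentile 38.6, of either sign depending on how probe sets are combined). At 2-fold, 7 of the 93 were higher and 9 lower. Over all detected genes 17.1% were 1.5-fold apart and 3.41% 2-fold apart. The receptor genes were kept by the higher of their 2 values, which favours large differences near the detection level, and the shares were not matched by level. Differences of these sizes do occur among dim genes that a stromal line is not thought to use.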

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

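Probe sets that the annotation does not name were not used in any gene or list result. They did enter the loess and quantile fits, the stricter level and the correlation across all probe sets. Among 7976 of them above the detection level on at least 1 array, 952 were at least 2-fold higher after anti-CD84 than after IgG1 and 695 were 2-fold lower. They were flagged for the number of higher ones, though the differences ran in both directions. Together 20.6% of these probe sets were 2-fold apart. Among detected named genes the share was 3.41%. The shares were not matched by level or by probe set, and why they differ was not tested, so the higher probe sets are not read as a response. Measured on both arrays, the widest differences were 3.32 (probe set 17378313) and 3.28 (17322483) upward and -4.08 (17203667) and -3.19 (17384447) downward.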

How the results depend on the processing

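Of the 8 alternatives, 1 (both arrays above the detection level) was added after seeing the data. Under all 8 the p53 list stood in the top 0.5% of its random lists and the small nucleolar RNA list in the bottom 0.5%, with medians from 0.37 to 0.46 and from -0.25 to -0.14. Counts depended on how dim genes were treated. The stricter level filter, which tests fewer genes, gave 142 genes 2-fold apart (113 higher, 29 lower) and 961 at 1.5-fold (742 higher, 219 lower). Flooring at the detection level gave 270 at 2-fold, of which 76 lower, and 550 lower at 1.5-fold. Requiring both arrays above it gave 232 at 2-fold (171 higher, 61 lower) and 457 lower at 1.5-fold. No level filter, which tests more genes, gave 302 lower at 2-fold and 1575 lower at 1.5-fold. Rescaling kept the totals within 1.5 times but moved the split at 2-fold from 58.1% higher to 42.7% (centred), 52.8% (loess) or 214 genes each way (quantile). At 1.5-fold it moved from 62.7% higher to 47.6%, 53.8% and 51.3%. Cox7b reversed, to 0.021, with the mean of its probe sets, since they differ in sign. Of 1183 alternative values of single genes 31 moved by more than 0.46, the spread among sensory receptor genes, 28 of them by flooring. Of 293 list values 61 moved by more than the spread of random lists, 18 of them by centring, which lowers every gene alike and leaves a list's percentile as it was, and 10 came to stand apart. Among the latter were SLAM (99.9) and chemokines (99.6) without a level filter, interferon response (up to percentile 99.8, in 2 alternatives), ribosomal proteins (down to 0.26, in 3) and osteoblast and chondrocyte markers (down to 0.06, in 3; up to 29.2 in another); the cause was not tested. Adding 16 before the logarithm was not run, since the table is already log2. No paired analysis was possible because each condition has 1 array. Low signal limits what can be said of Cd84, Cd274 and other genes near the detection level.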

Other observations

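The hypotheses in this part were formed after the data were seen, and all tests below except that on host transcripts were chosen or altered after the result was seen. Among genes outside the fixed naming rule, measured on both arrays and picked after their values were seen, those higher after anti-CD84 included Sned1 (2.99-fold), the Ras and Rab interactor Rin2 (2.91-fold), the long non-coding RNA Crnde (2.86-fold), the prostaglandin F receptor Ptgfr (2.73-fold) and Igfbp5, which binds insulin-like growth factors (2.69-fold). Those lower included Olfml3 (2.51-fold), geminin (Gmnn), which blocks the relicensing of replication origins (2.51-fold), Depdc1b (2.36-fold), the atypical NF-kB inhibitor Nfkbid (2.30-fold) and Lsm3, a component of RNA processing complexes (2.26-fold). The olfactory receptor Olfr1454 had the lowest difference of any gene measured on both arrays, -3.30 (6.19 against 9.48).

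Genes of the p53 response stood higher after anti-CD84, with Mdm2, Eda2r, Sesn1 and Cdkn1a leading and Ccng1 (0.45), Rrm2b (0.64), Plk3 (0.71) and Bbc3 (0.62) in the same direction, while Phlda3 (-0.26), Plk2 (-0.24) and Zmat3 (-0.19) were not. A level-dependent shift between the arrays is argued against as the whole cause: the loess correction took the list's median from 0.46 to 0.38, while 99% of random lists not matched on level then had medians between -0.23 and 0.26. Whether a few members only carry the shift was undecided by the limits set, with 75% of members (18 of 24) above the overall median, between 60% and 80%. Before the correction the list's median of 0.46 lay above the range of -0.12 to 0.32 that held 99% of level-matched random lists. That comparison is the one that set the list apart, so it adds no separate evidence on a few members. A later test on the median without the highest members was dropped, since a few members hardly move a median. A difference between single cultures or arrays unrelated to the antibody cannot be told apart from an effect of CD84 activation, because there is 1 array per group, so a p53 response to CD84 activation may be stated only as a hypothesis.

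For the lower small nucleolar RNAs after anti-CD84, a level-dependent shift between the arrays is argued against, since the loess correction took the list's median from -0.16 to -0.24, below the -0.12 to 0.16 that held 99% of random lists not matched on level. Lower recovery or labelling of short RNA in that sample may account for the pattern but stays a hypothesis. The 21 other short or miscellaneous non-coding RNAs had a median of -0.32. Among the 10 with established names the median was -0.35, with Rnu11 at -0.76, Rprl1 at -0.82 and Rpph1 at -0.28, although Terc was at 1.17. The 169 detected microRNA precursors had a median of 0.10. Over the alternatives that median ran from -0.005 to 0.10, at percentiles from 1.7 to 86.4, so the precursors do not decide the question. The set of 21 first held 26 genes (median -0.30) and was narrowed to leave out members of the small nucleolar RNA list. It still holds Rnu3a (U3), itself a small nucleolar RNA, without which the median of the other 20 was -0.30. Lower host transcripts are left open by the 14 detected Snhg transcripts, whose median was -0.036 (percentile 7.3 of random lists). That set holds only transcripts named Snhg, so it cannot decide for small nucleolar RNAs whose hosts have other names. A change in small nucleolar RNA itself was not tested apart from these.

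Because Zfp955a, Zfp974 and Zfp729a were among the named higher genes, with Zfp820 among the lower, a higher level of the class as a whole was tested over all 293 detected genes named Zfp and a number. Their median was 0.13 against 0.07 for random lists, at percentile 97.0, inside the bounds, with 47 members 1.5-fold higher and 19 lower. The class was therefore not set apart by the rule used for the other lists. This test replaced a pair of others, which put the class at percentile 96.7 after the loess correction and 61.7 among the 74 of its genes above 7 on both arrays.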
